A study of Homo sapiens with 4 samples.

How the data were processed

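Chromatin accessibility was measured in single nuclei by droplet ATAC-seq, an assay in which a transposase inserts sequencing adapters into open DNA, with the 10x Genomics single-cell ATAC kit, per the labels' protocols. The 4 libraries came from the established human breast cancer line SUM159 and from SUM159R, each treated for 12 h with the vehicle DMSO or with JQ1, a small molecule that displaces BET bromodomain proteins from acetylated chromatin. Each of the 4 groups had 1 library, taken from the library titles. The labels do not give the dose of JQ1 or say how SUM159R was derived. The protocols also name lines called SUM149 and SUM149R, which were not analysed here.

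Per the submitters' processing notes, the reads were handled with Cell Ranger and the hg19 build; the version, the aligner settings and the peak caller's settings are not given in the sources used here. The deposited values are raw counts per called peak and barcode, with peaks and barcodes listed separately for each library. Called peaks differed in position and width between libraries, so a region without a called peak in a library has no count there and was not treated as a 0. The highest peak end on chromosome 1 was 249219253, which lies within the hg19 length. Positions are given 1-based in hg19. The annotation at hand was of another build, so no gene names, promoters or sequence motifs were assigned, and regions are named by position. For the same reason promoter and distal regions were not separated.

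Most entries of the count tables were even. In the SUM159 DMSO library 61.2% of the non-zero entries were 2 and 14.1% were 1, as counting both ends of a fragment would give. Counting intervals were therefore computed from counts divided by 2. Intervals of shares and of ratios of counts are exact at the 95% level (Clopper-Pearson for shares, and the binomial form for the ratio of 2 Poisson counts) and cover counting error only. Intervals said to be over bins are the middle 95% of 1000 resamples of the 10 Mb bins. Both say nothing of the spread between cultures. Those computed from counts also leave out variation between cells beyond counting noise. Where 0 barcodes were found, the limit given is not such an interval but the share that 3 barcodes would make. With 1 library per group no test between conditions was run, no p-value is given, and each ratio compares libraries, not conditions. A model adding up line and treatment was not fitted, since it would take the difference in response between the lines as its error.

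Peaks of the 4 libraries were merged where they overlapped by at least 1 bp, which gave 146572 regions, of which 57446 held a called peak in all 4 libraries. Counts were summed over all barcodes of a library and scaled to CPM, counts relative to the total over these common regions; the matched regions described below were scaled to their own total. The 54273 regions with a mean of at least 50 raw counts over the 4 libraries were compared, and regions with a ratio of at least 2 were counted. A library at 0 counts in a region was set to 3 counts. The number that counting noise gives was simulated by drawing both libraries at equal rates, 20 times. These choices were made before the data were examined, as was the use of 50% matched regions as an alternative, in which each library has 1 peak and every pair of peaks overlaps by at least 50% of both. There were 36143 such regions past the count filter. A stricter set of 11602 regions with an overlap of at least 80% was added after the data had been seen.

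The rule for named regions, fixed before the data were examined, took the 10 highest and the 10 lowest ratios of each comparison. Over all common regions it picked regions in which 1 library had only a sliver of a called peak, with narrowest widths of 1 to 109 bp over the 80 places. The same rule was therefore also applied to the 50% matched regions, a decision made after the values were seen, and the regions named in the text come from there unless stated. The 5 regions with the highest and the 5 with the lowest ratio in both pairs of libraries were added at the same time.

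Median log2 ratios were taken over 10 Mb bins with at least 20 regions. Barcodes were clustered on the binarised common regions with term frequency-inverse document frequency weights, 30 components of a truncated singular value decomposition, 20 nearest neighbours and the Leiden method at resolution 0.5. The first component was left out because it followed depth (r = 0.970). Clusters were numbered and not named, and no doublet caller was run. Windows of 100 kb with at least 50% of their length inside called peaks in every library were listed as nearly covered.

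The comparison was tested on simulated counts for the 54273 regions with 200 of them altered. Of regions simulated 3-fold higher, 100% passed 2-fold for JQ1 against DMSO in SUM159, and of those 3-fold lower 92% did. Of those simulated 1.5-fold higher 0% did, and of those 1.5-fold lower 14% did. In that simulation 204 unaltered regions passed 2-fold. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. TMM factors, 1 of the alternatives for scaling, came from edgeR 4.0.16 in R 4.3.3.

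Other alternatives were median-of-ratios size factors, other count filters, binarised counts, filters on barcodes, thinning to equal cells and counts, regions called only in the libraries compared, a 1.5-fold threshold, 25 Mb bins, subtraction of the bin median, other overlap rules for peaks and other settings of the clustering.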

Results

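The 4 libraries were made to compare the response of SUM159 and SUM159R chromatin to BET bromodomain inhibition. SUM159 is an established triple-negative breast cancer line. The series concerns synthetic lethality with BET inhibitors and resistance to them, and SUM159R is understood here as its resistant derivative, although the labels give only its name. The SUM159 DMSO library held 1173 barcodes, 79583 called peaks and 21192328 counts. The SUM159 JQ1 library held 1311 barcodes, 81910 peaks and 20280935 counts. In SUM159R the DMSO library held 1300 barcodes, 121262 peaks and 29061676 counts, and the JQ1 library 942 barcodes, 100031 peaks and 17759367 counts. There were no replicates, so every difference below lacks a replicate check.

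More of the genome was called accessible in the SUM159R libraries. Called peaks covered 61.2 Mb in SUM159 DMSO and 62.1 Mb in SUM159 JQ1, against 111 Mb in SUM159R DMSO and 84.1 Mb in SUM159R JQ1. The counts per kb of called peak went the other way, at 346, 327, 262 and 211 in that order. Of the SUM159 DMSO peaks 90.7% (95% interval 90.5 to 90.9) overlapped a peak of SUM159R DMSO, whereas 55.7% (55.4 to 56.0) of the SUM159R DMSO peaks overlapped one of SUM159 DMSO. Within SUM159, 84.5% (84.3 to 84.8) of the JQ1 peaks overlapped a DMSO peak. Within SUM159R the share was 84.4% (84.1 to 84.6). In the other direction 86.8% (86.6 to 87.1) of the DMSO peaks overlapped a JQ1 peak in SUM159 and 66.4% (66.1 to 66.7) in SUM159R. The number of peaks depends on depth and on calling in each library, and these shares changed with the overlap rule.

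Regions called in both libraries of 1 line and in neither of the other numbered 14502 for SUM159R and 3519 for SUM159. The SUM159R-only region with the most counts, chromosome 11 from 71708564 to 71718918, held 1188 counts in DMSO and 455 in JQ1. In SUM159 it was chromosome 19 from 37340570 to 37342341, with 748 counts in DMSO and 825 in JQ1. Of the 5 SUM159-only regions with the most counts, all but 1 lay on chromosome 19. Median levels were low, at 2.15 CPM for SUM159R-only and 2.71 CPM for SUM159-only regions against 8.94 CPM for common regions. Regions called only in the JQ1 libraries of both lines numbered 787, and chromosome 12 from 104733295 to 104737938 had the most counts, 429 in SUM159 and 368 in SUM159R. Regions called only in the DMSO libraries of both lines numbered 2106, and chromosome 5 from 149783641 to 149787283 led them, with 108 counts in SUM159 and 426 in SUM159R.

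Barcodes fell into a low and a high group in each library. Below 3000 counts lay 37.9% (35.2 to 40.8) of the barcodes of SUM159 DMSO, 40.1% (37.5 to 42.8) of SUM159 JQ1, 40.5% (37.9 to 43.3) of SUM159R DMSO and 49.8% (46.5 to 53) of SUM159R JQ1. They held 1.1% to 2.0% of a library's counts, so the summed counts rest on the upper group. Its median count per barcode was 25880.5, 23137, 34576 and 35316 in that order.

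**Figure D1:**
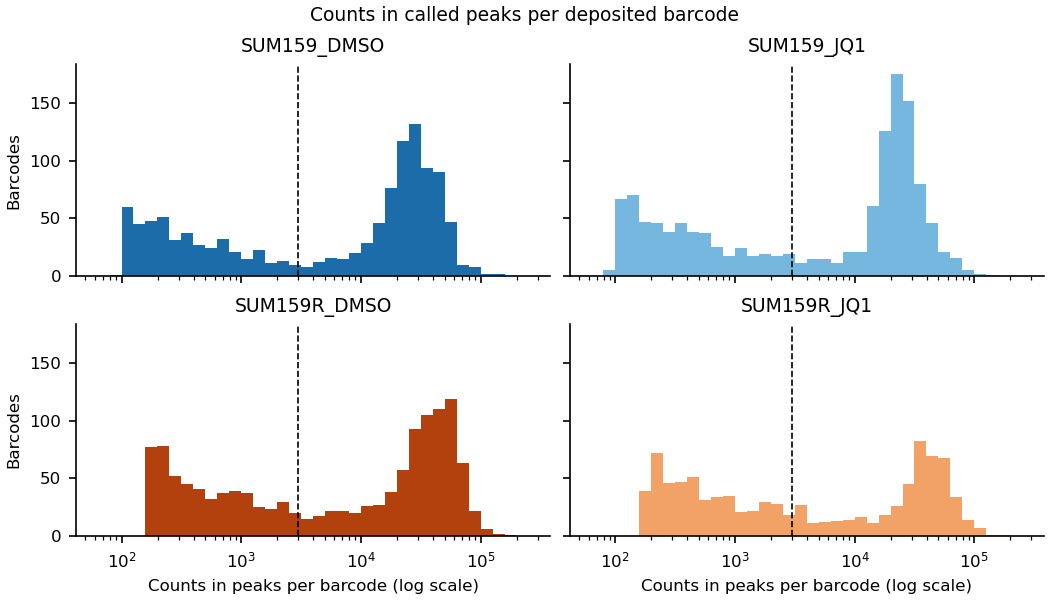
Number of barcodes (vertical axis) by counts in called peaks per barcode (horizontal axis, log scale) in the 4 libraries, with a dashed line at 3000 counts. Each library shows a low and a high group, and the low group is 37.9% to 49.8% of the barcodes.

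The first question was which regions differed after 12 h of JQ1 in SUM159. Among 50% matched regions the highest ratio was on chromosome 13 from 44762081 to 44763055, with 104 counts in DMSO and 357 in JQ1, 3.58-fold higher (2.6 to 4.96). Chromosome 2 from 71938198 to 71939109 was 3.36-fold higher (2.39 to 4.92) and chromosome 10 from 128128289 to 128129576 was 3.31-fold higher (2.51 to 4.34). The lowest ratios were on chromosome 12 from 120320202 to 120321229, 3.58-fold lower (2.52 to 5.14), with 313 counts in DMSO and 84 in JQ1, and on chromosome 2 from 208084464 to 208085281, 3.49-fold lower (2.31 to 5.49). The 10 highest regions spanned 2.96-fold to 3.58-fold and the 10 lowest 3.07-fold to 3.58-fold lower. In SUM159R 9 of these 10 highest and 10 of these 10 lowest regions had a ratio in the same direction, and 3 and 2 of them respectively passed 2-fold.

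Over all 54273 common regions, 2121 were at least 2-fold higher and 2298 at least 2-fold lower with JQ1 in SUM159, against 94.6 and 98.7 from counting noise. In the 36143 matched regions the numbers were 375 higher and 251 lower, against 19.9 and 20.6 from noise, so the balance of higher and lower regions turned around. It also turned around with the matched regions scaled to the total over all common regions in place of their own, which gave 403 higher and 234 lower. Over all common regions it turned around at 1.5-fold (5893 and 5218), without a count filter (2993 and 2890) and with barcodes within 0.5 and 2 times the median (2998 and 2818). Of the calls over all common regions 85.6% lay outside the matched set. Ratios of counts followed ratios of called width in matched regions too, at r = 0.781 across regions for JQ1 in SUM159, 0.726 for JQ1 in SUM159R, 0.783 for SUM159R against SUM159 in DMSO and 0.813 in JQ1. The median width ratio of matched regions past 2-fold, the library with the higher accessibility over the other, lay between 1.31 and 1.62 in the 4 comparisons. The folds of the regions named here were not corrected for called width. The highest ratio over all common regions, on chromosome 8 from 121094627 to 121095259, set 1 count in a 6 bp peak of the DMSO library against 185 counts in a 633 bp peak of the JQ1 library.

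In SUM159R the lowest ratio after JQ1 was on chromosome 5 from 54103180 to 54103926, with 207 counts in DMSO and 30 in JQ1, 4.66-fold lower (2.71 to 8.66). Its ratio in SUM159 was close to 1, from 72 and 69 counts. Chromosome 8 from 74331892 to 74332863 was 3.95-fold lower (2.48 to 6.61) and was also lower in SUM159, at a log2 ratio of -1.34. The highest ratio was on chromosome 1 from 99645776 to 99646467, 3.45-fold higher (2.14 to 5.48). Of the 10 highest regions 7 were also above 1 in SUM159, and of the 10 lowest 9 were below 1.

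Over all common regions 797 were at least 2-fold higher and 3225 at least 2-fold lower with JQ1 in SUM159R, against 89.9 and 153 from noise. The balance turned around with barcodes within 0.5 and 2 times the median (15216 and 7175), a filter that kept 382499 counts of SUM159R JQ1. Counting noise was not simulated for this filter, and with so few counts these numbers may be mostly noise. The matched regions gave 201 higher and 573 lower, against 43.8 and 76.5 from noise, and 275 and 426 when scaled to the total over all common regions. In the regions matched at 80% there were 7 higher and 6 lower, fewer than the 8.05 and 15 that noise gave, so no excess of 2-fold regions was found there. The SD of the log2 ratios in that set was 0.266, against 0.221 from noise.

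**Figure D2:**
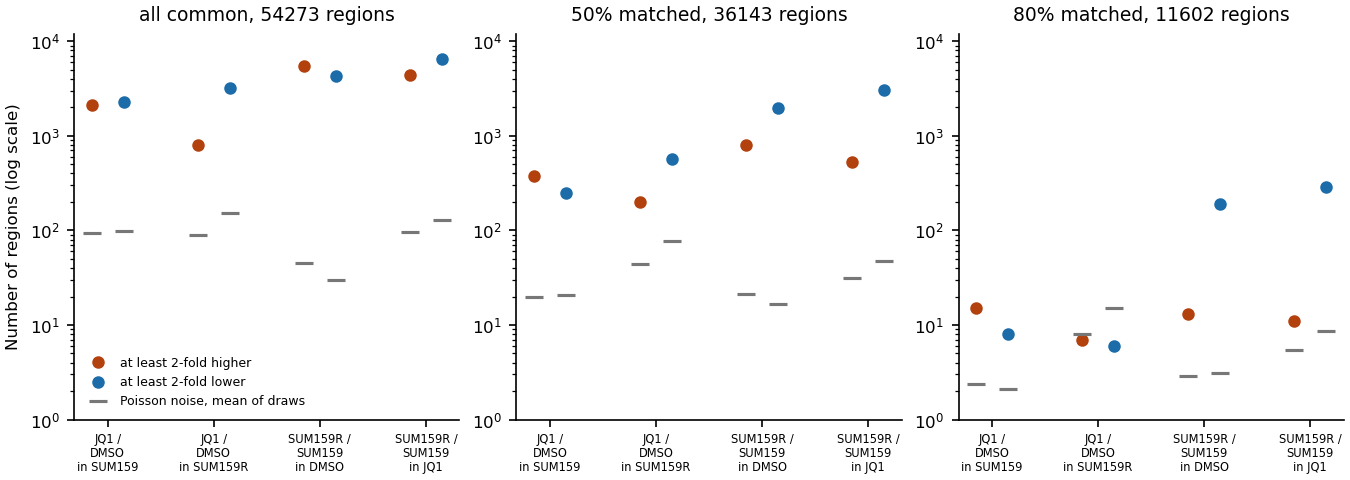
Number of regions at least 2-fold higher or lower (vertical axis, log scale) in the 4 comparisons, for all common regions and for regions matched at 50% and 80%; grey marks are the mean of 20 draws of counting noise. Numbers fall with stricter matching, from 2121 to 375 to 15 for regions higher with JQ1 in SUM159.

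The responses of the 2 lines to JQ1 were then set side by side, from ratios that share no library. Across regions, which are not replicates, the log2 ratios correlated at r = 0.289 (Spearman rho 0.283) in matched regions and at r = 0.209 (rho 0.289) over all common regions. In matched regions 21 were at least 2-fold higher in both lines, where independent lists give 2.09, and 28 were at least 2-fold lower in both, where independent lists give 3.98. The highest in both was chromosome 5 from 179543722 to 179544568, with log2 ratios of 1.31 in SUM159 and 1.30 in SUM159R. Chromosome 20 from 19966977 to 19967767 had 1.30 and 1.59. The lowest in both were chromosome 13 from 33823170 to 33823851, at -1.35 and -1.70, and chromosome 8 from 74331892 to 74332863, at -1.34 and -1.98.

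The difference of the log2 ratios, SUM159R minus SUM159, was at least 1 in 2009 common regions and at most -1 in 4824, against 447 and 523 from noise. In matched regions the numbers were 344 and 1252 against 209 and 250. In regions matched at 80% they were 25 and 56 against 43.0 and 49.8, fewer than noise gave for the former and slightly more for the latter, so the simulated noise was not a lower limit on such counts.

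Next, SUM159R was compared with SUM159 in DMSO. The highest ratios were on chromosome 5 from 44875476 to 44876562, 4.89-fold (3.67 to 6.63) with 112 counts in SUM159 and 622 in SUM159R, and on chromosome 2 from 31607136 to 31608590, 4.89-fold (3.84 to 6.33). The lowest were chromosome 19 from 6947612 to 6948187, 7.03-fold lower (4.47 to 12.2), and chromosome 10 from 106112922 to 106113850, 6.74-fold lower (5.01 to 9.23). All 20 named regions had the same direction in the JQ1 libraries, where 9 of the 10 highest and 10 of the 10 lowest passed 2-fold. Over all common regions 5482 were at least 2-fold higher and 4272 lower in SUM159R, and in matched regions 792 higher and 1946 lower, so the balance turned around here too. With matched regions scaled to the total over all common regions, 411 were higher and 2874 lower. With barcodes within 0.5 and 2 times the median, 7322 of all common regions were higher and 7886 lower. This filter kept 176 barcodes and 2443782 counts of SUM159R DMSO, and counting noise was not simulated for it. The balance over all common regions kept its direction with counts divided by called width (845 and 741). So it did with the number of barcodes in place of counts (2595 and 1333) and with at least 200 raw counts (1729 and 896). In regions matched at 80%, 13 were higher and 192 lower. Noise gave 45.5 and 30 over all common regions and 21.4 and 16.9 in matched ones.

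With JQ1 in both lines, the highest ratios were on chromosome 11 from 88512440 to 88513479, 5.23-fold (3.74 to 7.50), and on chromosome 2 from 181489257 to 181490615, 4.76-fold (3.42 to 6.96). The lowest were chromosome 16 from 16001654 to 16002399, 7.76-fold lower (4.90 to 13.8), and chromosome 17 from 56756087 to 56757519, 6.96-fold lower (5.09 to 9.48). Over all common regions 4359 were higher and 6435 lower, and in matched regions 523 and 3060, or 343 and 3849 when scaled to the total over all common regions. The balance turned around with a mean of at least 200 raw counts (1576 higher and 1117 lower), with the number of barcodes in place of counts (2530 and 1765) and with barcodes within 0.5 and 2 times the median (14326 and 7876). The ratios followed the level of a region: in matched regions the median log2 ratio was -0.37 in the lowest quintile of mean count and 0.10 in the highest, against -0.18 and 0.03 in DMSO.

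The difference between the lines was alike in both treatments. Log2 ratios of the DMSO pair and of the JQ1 pair, which share no library, correlated at r = 0.684 (rho 0.659) across matched regions. In these regions 208 were at least 2-fold higher in SUM159R in both pairs, where independent lists give 11.5, and 1139 were lower in both, where independent lists give 165. Chromosome 12 from 29718731 to 29720328 was highest in both, with log2 ratios of 2.04 and 2.24, and chromosome 10 from 106112922 to 106113850 lowest, with -2.75 and -2.62. Over all common regions the median called width was 1020 and 857 bp in SUM159R, DMSO first, against 689 and 694 bp in SUM159. Ratios follow called width, so peak calling shared by the libraries of a line may add to this likeness.

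Whole chromosome parts were shifted between the lines. In matched regions the median log2 ratio of SUM159R to SUM159 on chromosome 17 from 20 to 90 Mb was -0.49 in DMSO and -0.47 in JQ1 over 1564 regions. The X chromosome from 0 to 140 Mb had -0.48 and -0.50 over 1097 regions, chromosome 4 from 110 to 190 Mb -0.49 and -0.48 over 611 regions, and chromosome 13 from 20 to 50 Mb -0.62 and -0.77 over 446 regions. Chromosome 20 from 50 to 60 Mb was higher, at 0.62 and 0.59 over 103 regions, and chromosome 2 from 0 to 10 Mb at 0.48 and 0.50 over 48 regions. On chromosome 20 from 60 to 70 Mb, where fewer than 20 regions were matched, the median over 172 common regions was 1.26 and 1.30, whereas no matched bin went past 0.69 in DMSO or 0.77 in JQ1 in either direction.

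The bin medians of the 2 line comparisons correlated at r = 0.945 across 292 bins in matched regions. Their SD was 0.24 in DMSO and 0.23 in JQ1, against 0.06 and 0.05 for the JQ1 comparisons, in which no bin reached 0.3. In matched regions 19 bins were higher and 38 lower by at least 0.3 in DMSO, and 12 and 48 in JQ1. In regions matched at 80% there were 24 lower bins in DMSO and 26 in JQ1 and 0 higher ones in both, and the named bins on chromosomes 20 and 2 had fewer than 20 such regions. In matched regions with called widths within 5% of each other, bins that were lower in the other treatment were shifted by -0.15 in DMSO and -0.18 in JQ1 against unshifted bins. The shift of these bins was -0.355 and -0.328 in regions matched at 80% and -0.553 and -0.533 over all common regions. The lower blocks held 12.0% of the matched regions and 29.3% of those at least 2-fold lower in DMSO. After the bin median was subtracted, 790 matched regions were at least 2-fold higher and 1534 lower in DMSO, and 589 and 2302 in JQ1. Of the 20 named regions, 12 in DMSO and 11 in JQ1 were then still among the 10 highest and 10 lowest.

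**Figure D3:**
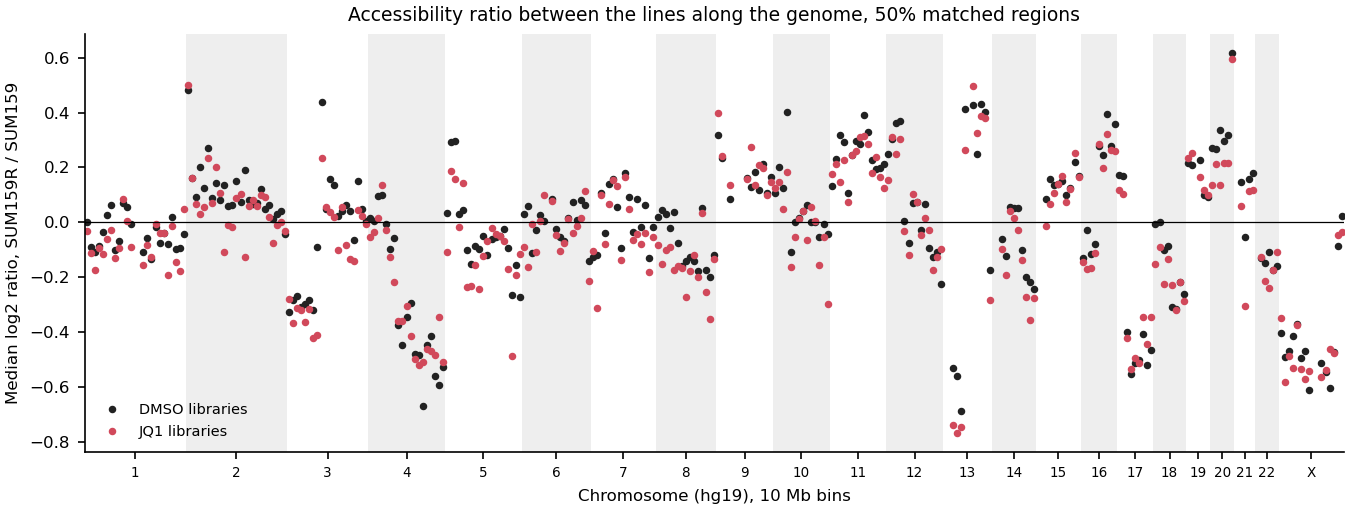
Median log2 ratio of SUM159R to SUM159 (vertical axis) of 50% matched regions in 10 Mb bins along the hg19 chromosomes (horizontal axis), for the DMSO libraries (black) and the JQ1 libraries (red). Chromosome 17, the X chromosome, chromosome 4 from 110 Mb and the first bins of chromosome 13 lie below 0 in both pairs.

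Clustering of all barcodes gave 6 clusters, of which clusters 1 and 2 were mostly barcodes under 3000 counts (89.1% and 77.3%). Cluster 3 held 47.5% (44.8 to 50.3) of SUM159R DMSO and 36.6% (33.5 to 39.8) of SUM159R JQ1. Cluster 4 held 47.6% (44.7 to 50.5) of SUM159 DMSO and cluster 5 44.2% (41.5 to 46.9) of SUM159 JQ1. Cluster 6 held 11.9% (10.1 to 13.9) of SUM159 DMSO and 11.8% (10.1 to 13.7) of SUM159 JQ1. It held 0 of 1300 barcodes of SUM159R DMSO and 0 of 942 of SUM159R JQ1. Few barcodes under 3000 counts fell into it (1.7% of its members). Over the 773 and 473 barcodes with at least 3000 counts, 0 allows a share of up to 0.388% and 0.634% in this cluster. That does not show that SUM159R lacks such cells. With 1 library per group, a cluster made mostly of 1 library can be that library and not a kind of cell.

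On chromosome 8 from 128000001 to 129200000, called peaks covered 88.6% of the sequence in SUM159 DMSO, 90.7% in SUM159 JQ1, 96.4% in SUM159R DMSO and 96.8% in SUM159R JQ1. This block held 2.65% (2.64 to 2.66), 2.78% (2.77 to 2.79), 2.29% (2.29 to 2.30) and 2.51% (2.5 to 2.52) of all counts in that order. These intervals treat fragments as independent. The block's share varied between cells with a CV of at least 0.610 beyond counting noise, so the intervals are too narrow for comparing libraries. The block's widest single peak was 346120 bp long, in SUM159R DMSO. Chromosome 5 from 2600001 to 2800000 was covered at 81.8% to 92.1%, and chromosome 5 from 3800001 to 4100000 at 71.0% to 83.0%.

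**Figure D4:**
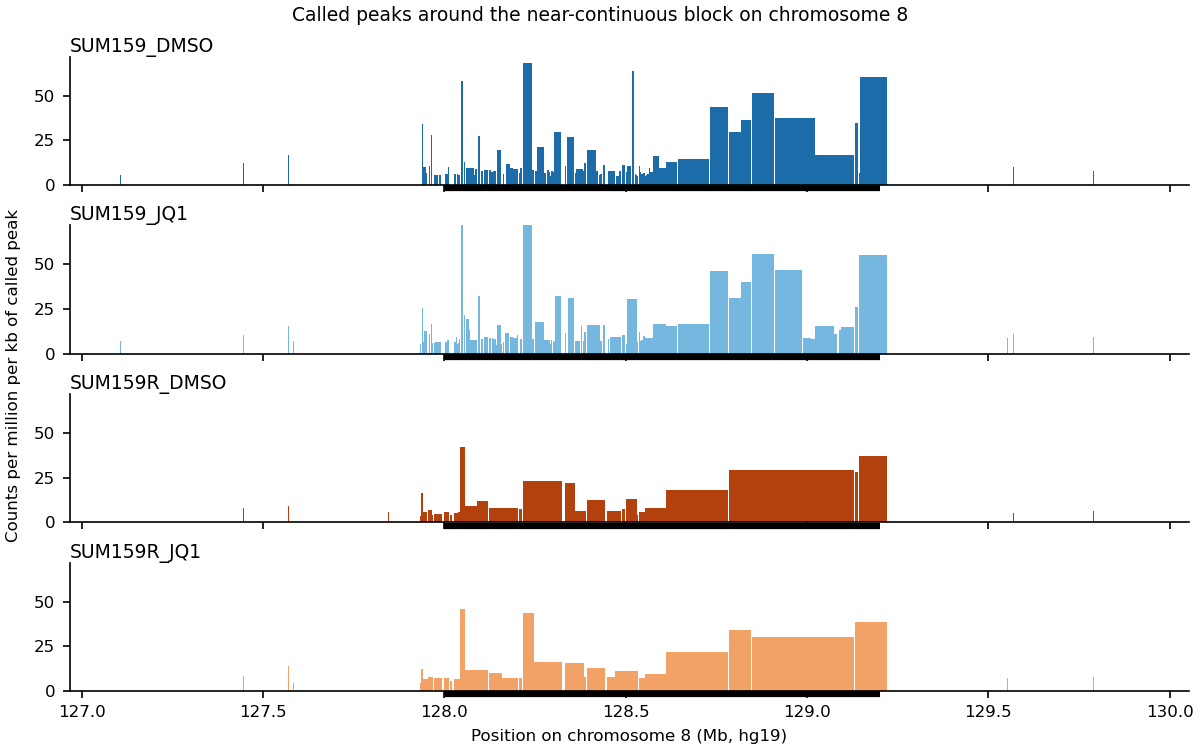
CPM per kb of called peak (vertical axis) along chromosome 8 (horizontal axis, Mb, hg19) in the 4 libraries; bars span the called peaks and the black line marks 128000001 to 129200000. Called peaks fill 88.6% to 96.8% of the marked block.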

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

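The regions in this part were picked after their values were seen. In 5 matched regions JQ1 went with a ratio of at least 2-fold in opposite directions in the 2 lines, higher in SUM159 and lower in SUM159R each time, and both counting intervals left out 1. Independent lists would give 7.34 such regions among the 36143, so 5 is no excess, and the difference between the lines was not tested, since each group had 1 library. The difference of log2 ratios, SUM159R minus SUM159, was -2.26 on chromosome 1 from 159721708 to 159722376, where counts were 80 and 163 in SUM159 and 90 and 27 in SUM159R, DMSO first. It was -2.56 on chromosome 11 from 82730816 to 82731458, -2.48 on chromosome 2 from 223957984 to 223958626, -2.49 on chromosome 7 from 90092301 to 90093111 and -2.54 on chromosome X from 13676722 to 13677551. Groups of 1 library gave no way to look for a library that stands apart from its group.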

How the results depend on the processing

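No paired analysis was possible because each group had 1 library, so no 2 groups shared 2 replicate numbers; lines taken as pairs across treatments, or treatments across lines, were not tested. The alternatives added after the data had been seen were the 80% matched regions, the counts divided by called width, the barcodes with at least 3000 counts, the bins in 50% and 80% matched regions, the 50% matched regions scaled to the total over all common regions, and the bin correction of regions named in the matched set. Gene list medians, motif shares and the split into promoter and distal regions were planned and not run, because the annotation and genome of the build were not used here. Another scaling (TMM factors or median-of-ratios size factors) kept all counts within 1.5 times the main ones, and so did subtracting the bin median in the line comparisons, after which 18 to 20 of the 20 regions named over all common regions were still named. Of the 20 named in 50% matched regions, 19 and 16 were still named in the JQ1 comparisons but only 12 and 11 in the line comparisons, in DMSO and JQ1. The numbers below give regions past 2-fold, higher then lower, for JQ1 against DMSO in SUM159, then in SUM159R, then SUM159R against SUM159 in DMSO, then in JQ1, and then regions whose JQ1 log2 ratios differ by at least 1 between the lines, SUM159R minus SUM159. The values over all common regions were 2121 and 2298, 797 and 3225, 5482 and 4272, 4359 and 6435, with differences in 2009 and 4824. With a mean of at least 200 raw counts they were 260 and 506, 38 and 325, 1729 and 896 and 1576 and 1117, with differences in 286 and 471. In 50% matched regions they were 375 and 251, 201 and 573, 792 and 1946 and 523 and 3060, with differences in 344 and 1252. Scaled to the total over all common regions, these gave 403 and 234, 275 and 426, 411 and 2874 and 343 and 3849, with differences in 414 and 1057. With counts replaced by the number of barcodes with a count they were 458 and 910, 101 and 656, 2595 and 1333 and 2530 and 1765, with differences in 680 and 961. In 80% matched regions they were 15 and 8, 7 and 6, 13 and 192 and 11 and 290, with differences in 25 and 56. With counts divided by the called width they were 264 and 309, 115 and 341, 845 and 741 and 650 and 1062, with differences in 472 and 719. At 1.5-fold they were 5893 and 5218, 3115 and 7534, 10297 and 10029 and 8375 and 12661. Matching of peaks and division by width act on the widths of called peaks, and stricter counts test fewer regions; the cause of the other changes was not tested. The filter on barcodes within 0.5 and 2 times the median kept 382499 counts of SUM159R JQ1, whose median barcode lay in the gap between the low and the high group. It gave 15216 higher and 7175 lower for JQ1 in SUM159R, 7886 lower for SUM159R against SUM159 in DMSO, 14326 higher in JQ1, differences in 15414 and 8520, and a correlation of 0.092. With barcodes of at least 3000 counts instead, all of these stayed within 1.5 times the main counts. Without a count filter 1265 regions were higher with JQ1 in SUM159R, after thinning 2140 were lower there, and in regions called in the 2 libraries compared 5987 were lower. With at least 200 raw counts the correlation of JQ1 log2 ratios was 0.400, against 0.209. The SD of bin medians between the lines fell from 0.293 to 0.172 in DMSO and from 0.291 to 0.173 in JQ1 in 80% matched regions. Peak overlap, for SUM159 JQ1 in SUM159 DMSO, SUM159 DMSO in SUM159 JQ1, SUM159R JQ1 in SUM159R DMSO, SUM159R DMSO in SUM159R JQ1, SUM159R DMSO in SUM159 DMSO, SUM159 DMSO in SUM159R DMSO, SUM159R JQ1 in SUM159 JQ1, SUM159 JQ1 in SUM159R JQ1, was 73.7%, 75.8%, 62.1%, 51.2%, 40.4%, 61.6%, 51.1%, 62.4% in that order with a reciprocal overlap of at least 50%, and 89.7%, 89.6%, 90.1%, 87.8%, 79.5%, 83.7%, 81.1%, 83.3% among the 40000 peaks with the most counts. A line led a cluster where its mean share was higher, so nearly even clusters count too, such as cluster 1 with 24.3% to 29.7% of each library. Barcodes were counted in each library's own called peaks, so clusters can also follow peak calling. The share of barcodes in clusters led by their own line, 73.9% in SUM159R DMSO and 72.8% in SUM159R JQ1, was 89.4% and 90.4% at resolution 1.0, and 76.7% in SUM159R DMSO with 15 components. With barcodes within 0.5 and 2 times the median it was 94.5% in SUM159 JQ1, 100% in SUM159R DMSO and 99.2% in SUM159R JQ1. With at least 3000 counts it was 93.7% in SUM159 DMSO, 94.8% in SUM159 JQ1, 100% in SUM159R DMSO and 99.8% in SUM159R JQ1. In simulated counts at these depths 0% to 14% of regions altered 1.5-fold passed the 2-fold threshold.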

Other observations

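In this part the tests of the near-continuous block against background reads and uneven copies, of the shifted bins against copy number, and of long stretches under JQ1 were set down before their results were seen. All the others were chosen after a result was seen: those on peak widths, on a minority of cells, on local gains, on calling in single libraries, on the blocks being carried together, on the group of SUM159 cells and on the response shared by the 2 lines. Earlier tests of local gains, of a minority of cells and of calling in single libraries were replaced, because the choice of bins, midpoint or windows fixed or nearly fixed their outcome, and those of peak widths because the first joined higher and lower blocks and in the second the choice of regions with equal widths lowers any shift.

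The regions in the largest stretches of neighbouring accessible regions had slightly lower ratios after JQ1. Common regions with gaps of at most 12.5 kb were joined, and the 500 stretches with the most counts, without the blocks on chromosomes 8 and 5, held 2028 matched regions. Their median log2 ratio was -0.049 in SUM159 and -0.029 in SUM159R. In 10000 random lists matched on mean count the middle 95% ran from -0.007 to 0.018 in SUM159. In SUM159R it ran from 0.001 to 0.028, and both medians lay below every list drawn. The lists drew single regions and were not matched on called width, which ratios follow at r = 0.781 and 0.726. Neighbouring regions can share a shift, so the spread of the lists may be too narrow. All other matched regions had medians of 0.033 in SUM159 and -0.016 in SUM159R. The shift is small. The direction is that of the hypothesis that long clusters of open regions lose more accessibility under BET inhibition. These lists cannot decide it, and the values describe these libraries only.

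A response to JQ1 shared by the lines was the other hypothesis. Regions past 2-fold in both lines exceeded independent lists by at least 7.04 times in matched regions, in higher and in lower ones. Over all common regions the excess was 4.78 times for higher and 4.46 times for lower ones, and regions past 2-fold in opposite directions exceeded independent lists as well, with 200 against 160; in matched regions these were 5 against 7.34. Peak widths that follow treatment may add to this excess. With counts divided by called width, the log2 ratios of the 2 lines correlated at r = 0.134 over all common regions, against 0.209 without. Regions matched at 80% had too few calls to look for shared ones. There the log2 ratios correlated at r = 0.283, against 0.289 in those matched at 50%. Ratios at 80% still followed called width, at r = 0.646 in SUM159 and 0.564 in SUM159R.

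For the blocks shifted between SUM159R and SUM159, bins were chosen in the other treatment arm. A per-cell score was the log2 ratio of counts in higher bins to counts in lower bins. At least 92.6% of SUM159R cells lay beyond the 95th percentile of SUM159 cells in it. Called widths in matched regions were shifted too, by log2 -0.198 in lower and 0.155 in higher blocks in DMSO. In JQ1 these width shifts were -0.143 and 0.144. Wider peaks raise the counts of all cells of a library alike. The score therefore shows a shift of counts in most cells, but cannot decide whether a minority of cells caused it. That gains and losses at only a part of the regions carry the shift is argued against. In lower blocks, the decile of matched regions farthest from a block's direction had at least 0.761 (0.631 to 0.861 over bins) of the median's shift. In higher blocks it had at least 0.842 (0.600 to 1.283). The shift of called widths can move all regions of a block, so local changes beside it stay open. Peak widths as the whole cause are argued against for the lower blocks. In regions with called widths within 5% of each other, a shift beyond that of the widths was left. It was -0.133 (-0.146 to -0.117 over bins) in DMSO and -0.173 (-0.196 to -0.144) in JQ1. The 80% matched regions kept 0.642 and 0.615 of the shift over all common regions. Their called widths were still shifted, by log2 -0.073 and -0.059. Regions with widths within 5% kept 0.263 and 0.346, but choosing equal widths lowers any shift. The part that widths have in the lower blocks stays open. For the higher blocks, at 0.137 (-0.081 to 0.367) and 0.092 (0.044 to 0.147), widths as the whole cause stay open too. The bin medians of the weakest and the strongest regions, by tertile of mean count, correlated at r of at least 0.763, as a different number of DNA copies in the 2 lines would give, and such a difference may itself change called widths. Copy number is thus a candidate explanation, with no DNA measurement here to set beside it, and broad regulation of whole chromosome parts stays open too.

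For the near-continuous peaks on chromosome 8, wider calling in single libraries is argued against: the longest run of windows covered by at least 50% in any 1 library lay there, and at least 84.8% of it was inside peaks in each of the other libraries, whereas of the 81 other windows so covered in SUM159R DMSO 5 were covered in all 4. The block's share of counts varied between cells beyond counting noise with a CV of at least 0.610. All stretches of similar total count lay below that, with a highest CV of 0.431. Each library held only 24 to 29 of them, so they were much longer than the block. Averaging over that length can lower their CV, so they cannot show that the block is unusual. Among windows of its own length, the block lay above the 95th percentile in each library (0.307 to 0.575, cells with at least 3000 counts). The block lay below the most variable window, whose CV was 1.57 to 2.33. Across cells with at least 20000 counts, its share correlated at rho of at least 0.670 with that of chromosome 5 from 2600001 to 2800000 and of at least 0.604 with that of chromosome 5 from 3800001 to 4100000, above the 0.528 that was the highest of any window outside these 3 blocks. The first of these had been seen before the test on background reads was set down; with each cell's share in the sparsest peaks, the lowest tertile of counts per bp, held fixed it was still at least 0.622, which argues against them. A hypothesis is that these blocks are present in extra DNA copies that are carried together and unevenly by cells, which no DNA measurement here can settle.

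Some 1.2 Mb windows varied more than the block on chromosome 8. In cells with at least 20000 counts the most variable was chromosome 5 from 3600001 to 4800000, which holds the last of the 3 blocks, with a CV of 1.74 in SUM159 DMSO, 2.41 in SUM159 JQ1, 1.62 in SUM159R DMSO and 1.96 in SUM159R JQ1, against 0.562, 0.861, 0.669 and 0.792 for the block on chromosome 8. Also above it were chromosome 5 from 2400001 to 3600000, which holds another of the blocks, at 0.719 in SUM159 DMSO, 0.703 in SUM159R DMSO and 0.942 in SUM159R JQ1, chromosome 5 from 1200001 to 2400000 at 0.712 in SUM159R DMSO and 0.913 in SUM159R JQ1, and chromosome 7 from 2400001 to 3600000 at 0.794 in SUM159R JQ1. The MYC gene is known to lie on the part of chromosome 8 that includes the block. Which genes the block holds was not analysed here.

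Among barcodes with at least 3000 counts, a clustered group held 144 of 728 SUM159 DMSO cells (19.8%) and 154 of 785 SUM159 JQ1 cells (19.6%). It held 0 of 773 SUM159R DMSO cells, which allows up to 0.388%, and 0 of 473 SUM159R JQ1 cells, which allows up to 0.634%. These limits are for membership of the cluster. Clusters at this depth split mostly by library, and SUM159R cells were not scored for the profile of the group. Whether SUM159R holds such cells was therefore not tested. Medians of the group were higher on chromosome 7 (log2 0.40 and 0.36), chromosome 20 (0.44 and 0.43) and chromosome 5 from 60 Mb (0.32 and 0.34). Chromosome 17 was raised less (0.13 and 0.14). Chromosome 3 was lower (-0.22 and -0.28), against a median over all bins of -0.09 and -0.10. Single bins were lower still, as on the X chromosome from 60 to 70 Mb (-0.66 and -0.62) and chromosome 9 from 0 to 10 Mb (-0.65 and -0.55). The X chromosome bins from 0 to 40 Mb had -0.39 to -0.43 in SUM159 DMSO and -0.29 to -0.49 in SUM159 JQ1. Grouping from odd chromosomes alone found 140 of the 144 and 151 of the 154 cells again. Cells so grouped had a ratio of at least 0.451 on chromosome 20, outside the -0.14 to 0.05 of the other even chromosomes. The X chromosome lay inside that range at -0.11 and -0.13. Chromosome 20 was already known to be high in these cells, so this outcome was nearly fixed. It shows that the group can be found without chromosome 20. Other DNA copy numbers may account for the group, which this test cannot decide. Depth is argued against by a median count that differed by at most 1.13 times. The group's bin profile and the difference between the lines correlated at r of at most 0.104. This argues against the group as the cells from which SUM159R arose, unless that profile changed later. Both were higher on chromosome 20, but opposite on chromosome 17 and chromosome 5 from 60 Mb. On the X chromosome as a whole the line difference was -0.47 in DMSO and -0.51 in JQ1. The group was at -0.13 in SUM159 DMSO and -0.15 in SUM159 JQ1 there, near its median over all bins. Without chromosome 20 and the X chromosome r was -0.080 and -0.057. Called widths differ between the lines but not within a library, which can lower this correlation.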
